A study of Homo sapiens with 6 samples.

How the data were processed

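The series holds 6 Affymetrix arrays of the human U133 Plus 2.0 kind, hybridised with biotin-labelled cRNA from total RNA of A375 cells, per the labels. The deposited values are RMA intensities on a linear scale, from 3.01 to 19000, with array medians of 36.7 to 37.3; RMA and the affy package are named in the submitters' processing notes, and their versions were not given in the sources used here. RMA corrects background, quantile-normalizes the arrays together and summarises the probes of each probe set. It compresses changes of very dim and very bright probe sets, and it forces the arrays to nearly the same distribution, so a change in total mRNA per cell would not be seen. The design had assumed values already on the log2 scale; since they were linear, log2 was taken first. The number of arrays limits the precision. RNA quality signs were alike: GAPDH and ACTB control probe sets differed between their 3' and 5' ends by -0.01 to 0.04 and 0.13 to 0.18 log2 units.

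Of 54675 probe sets, 62 are array controls and stayed out, 41091 carry 1 gene symbol in the platform annotation, 1801 carry several and name no gene here, and 11721 are unnamed here. Symbols were looked up through gene identifiers in RefSeq's GRCh38.p14 gene table; 41037 of the single-gene probe sets matched, 54 kept the annotation's symbol, and 0 symbols changed. Each of 19775 genes was represented by the probe set with the highest mean over the 6 arrays, and 13506 genes with a mean of at least 5 log2 units were tested. List members without such a probe set were not analysed here.

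Samples were grouped by line and treatment from the labels, 1 array each. The main model was an additive fit of line and treatment over all 6 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 2 residual degrees of freedom plus 3.19 from the prior), with contrasts for 6 h against vehicle, 18 h against vehicle, 18 h against 6 h and knockout against rescued, Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The difference between the lines in their response has no residual degrees of freedom at a single time and was reported as a value, with a size of 1 log2 unit (2-fold) counted. A term for that difference shared by 6 h and 18 h, with 1 residual degree of freedom, was added after the data were examined. Positive differences between the lines mean higher in the knockout line.

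Before the data were examined, 23 gene lists were fixed: ERK output, ATF4 and the integrated stress response, ER chaperones, G1/S, G2/M, cell cycle inhibitors, pigment cell genes, undifferentiated melanoma, receptor tyrosine kinases, translation initiation factors, ribosomal proteins, ribosome biogenesis, cholesterol synthesis, BCL2 family, p53 targets, glycolysis, oxidative phosphorylation, interferon, NF-kB, lysosome, and markers of epithelial cells, fibroblasts and blood cells. Some genes are in more than 1 list. The ribosomal protein list also holds other mRNAs of the 5' TOP class, such as EEF2 and TPT1. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over 92 list and contrast pairs. With the correlation estimated for each list, 0 of the 43 calls held. The estimates reached 0.73, for the ATF4 list, and the test then also has fewer degrees of freedom. Lists with an estimate below the preset value lost their calls too. For G1/S at 18 h, with an estimate of 0, the unadjusted camera p went from 6.5e-14 to 0.015, and the NF-kB list had an estimate of -0.02. For such lists the loss is therefore no sign of gene correlation. For lists with higher estimates the 2 were not separated. For single arrays and untested differences a list's median was placed among 10000 random lists matched in 20 bins of mean expression, as a description.

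Genes were named by a rule set before the data were examined. For 6 h and for 18 h they were the 12 highest and 12 lowest mean changes among genes past the threshold that changed by at least 1 log2 unit the same way in both lines, and for 18 h against 6 h the first 6 each way. Between the lines they were the 12 highest and 12 lowest past the threshold with the same sign in all 3 pairs, and for each difference in response the 8 most positive and 8 most negative with a mean of at least 6. Up to 4 members per list and contrast and EIF4B were added, and predicted loci were passed over. Members named to complete or explain a count of 5 or fewer (DDIT3, KLF6, PPP1R15A and SPRY1), examples given in a contrast other than the one the rule picked them for, and genes taken from the added test were chosen after their values were seen.

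The fit was tested on simulated data with the real gene means and variances drawn from the fitted prior, 13506 genes in all. Genes were simulated independently, and 66 or 67 were changed at each size. Far more genes were called at 6 h and 18 h, so recovery in the real data may differ. For 6 h against vehicle it recovered 43.3% of genes changed by 0.5 log2 units, 89.6% by 1 and 98.5% by 2; for 18 h 43.3%, 97.0% and 100%; and between the lines 58.2%, 95.5% and 100%. The alternatives set beforehand were probe sets averaged per gene, probe sets that can match several transcripts left out, no filter or a filter at 6, arrays centred on their medians, cyclic loess, a trended and robust prior, a minimum change of 0.5, fits of 4 arrays and leaving out each pair. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.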

Results

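Genome-wide mRNA levels were measured on 6 Affymetrix arrays in A375, a human melanoma cell line that carries an activated BRAF kinase and depends on BRAF signalling. The gene for eIF4B, an RNA-binding cofactor of the translation initiation helicase eIF4A, had been knocked out by CRISPR, and the knockout cells were then transduced with LacZ (KO/LacZ, the knockout line) or with wild-type eIF4B (KO/eIF4B, the rescued line). Each of the 2 lines received vehicle, 10 µM vemurafenib for 6 h or 10 µM vemurafenib for 18 h. Vemurafenib inhibits mutant BRAF and so lowers ERK signalling. There was 1 array per combination of line and treatment, which limits the precision. The labels give no time for the vehicle arrays, so effects of time in culture are not separated from those of the drug. This holds against vehicle and between 18 h and 6 h. The labels do not say whether the arrays came from separate cultures, so p-values measure the spread between these arrays only. Array medians lay between 5.196 and 5.221 on the log2 scale, and 13506 genes were tested.

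The targeted gene was examined first. The EIF4B probe set with the highest signal read 8.40, 8.53 and 8.53 (log2) in the knockout line under vehicle, 6 h and 18 h, and 10.07, 10.14 and 10.28 in the rescued line. The knockout line was lower in all 3 pairs of arrays, 3.2-fold on average (log2 difference -1.68, SE 0.05, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0056). The other 2 EIF4B probe sets did not separate the lines that way. Their log2 differences, knockout minus rescued, were 0.19 and 0.17, with limma Benjamini-Hochberg adjusted p-values of 0.39 and 0.41 over all probe sets. A CRISPR knockout need not lower the mRNA, and the part of the transcript that each probe set matches was not analysed here. These levels check which line carried the extra eIF4B sequence and not the loss of the protein.

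**Figure D1:**
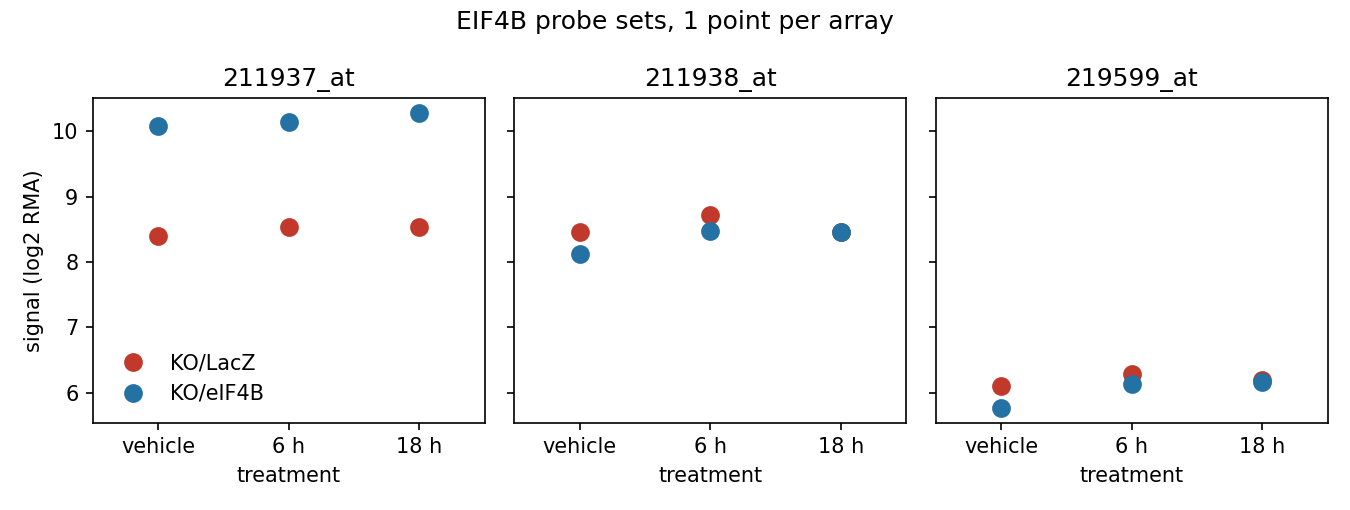
Signal of the 3 EIF4B probe sets (y axis, log2 RMA values) under each treatment (x axis), 1 point per array, knockout line in red and rescued line in blue. Only the brightest probe set separates the lines, with 8.40 to 8.53 in the knockout line and 10.07 to 10.28 in the rescued line.

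The first comparison asks what 6 h of vemurafenib changed in both lines. Feedback regulators and targets of ERK signalling fell. DUSP6, a phosphatase that inactivates ERK, changed by -5.19 log2, the largest fall (SE 0.10; -5.33 in the knockout line and -5.05 in the rescued line), and SPRY2, a feedback inhibitor of receptor signalling, by -3.67. IER3 (-3.67), MAFF (-3.66) and the ETS transcription factor ETV5 (-3.49) fell similarly, as did ESM1 (-4.28), ANKRD1 (-3.68), TLR4 (-3.36), SHISA2 (-3.33) and PTX3 (-3.16). Of the 25 genes of the ERK output list, 24 fell and SPRY1 alone missed the threshold at -0.28, while all 25 passed when adjusted over the list alone. The list median was -2.39 (camera in limma, Benjamini-Hochberg adjusted p = 1.2e-26, and adjusted p = 0.50 with an estimated correlation). Inflammatory mediators fell as well: the chemokines CXCL1 and CXCL8 changed by -3.57 and -3.44 and the cytokine IL24 by -2.68. In that NF-kB list 4 of 11 members fell and 1, the inhibitor NFKBIA, rose by 0.55, against 6 and 2 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.0025, and adjusted p = 0.61 with an estimated correlation).

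The 2 largest increases at 6 h were in transcription factors. FOXD3, a neural crest factor, rose by 3.99 (SE 0.29; 3.62 in the knockout line and 4.37 in the rescued line) and SOX2, a pluripotency factor, by 3.36 (SE 0.10). DACT1 (2.83), VGLL3 (2.71), ST8SIA4 (2.70), ECM2 (2.61), CD24 (2.56), PCDH10 (2.49), GASK1B (2.44) and STON1 (2.42) followed. MITF, the master regulator of pigment cells, rose by 1.01 and SOX10 fell by 0.63. In the pigment cell list 1 of 13 tested members rose and 2 fell, against 2 and 2 adjusted over the list alone. The tested members showed no shift (camera in limma, Benjamini-Hochberg adjusted p = 0.80). The list has 22 genes. TYRP1, MLANA, GPR143 and TRPM1 were among those too dim to be tested, and DCT had no single-gene probe set. List results here and at 18 h therefore do not cover them.

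Targets of ATF4, the transcription factor of the integrated stress response, rose at 6 h. JDP2 rose by 2.32, CHAC1, which degrades glutathione, by 1.95, and PSPH, an enzyme of serine synthesis, by 1.48. Of 33 members tested 11 rose and 1, PPP1R15A, fell, against 19 and 1 adjusted over the list alone, and the list median was 0.47 (camera in limma, Benjamini-Hochberg adjusted p = 6.8e-06, and adjusted p = 0.64 with an estimated correlation). CTH, a cysteine-making enzyme outside the list, rose by 2.16. In the list of ER chaperones, the other branches of the unfolded protein response, 1 of 19 members rose (HERPUD1, 0.57) and 4 fell, EDEM1 by 0.50 and MANF by 0.42 among them, against 1 and 5 adjusted over the list alone, with no shift of the list (camera in limma, Benjamini-Hochberg adjusted p = 0.58).

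Glucose uptake and glycolysis genes were among those lowered at 6 h: the glucose transporters SLC2A3 and SLC2A1 changed by -2.35 and -1.26, PFKFB3 by -1.02 and hexokinase HK2 by -0.74. In that list 6 of 22 members fell and 0 rose, against 7 and 0 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.013, and adjusted p = 0.61 with an estimated correlation). MCL1, an inhibitor of apoptosis, fell by 1.31 in both lines and BCL2L1 fell by 0.64, while HRK, which promotes apoptosis, rose by 0.59. In the BCL2 family 2 of 13 members rose and 3 fell, against 2 and 4 adjusted over the list alone, with no shift (camera in limma, Benjamini-Hochberg adjusted p = 0.086). Among cell cycle genes, CDC25A (-0.94), CCNE2 (-0.77) and CCNE1 (-0.58) fell, with 7 of 27 G1/S genes lower and 8 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.0089, and adjusted p = 0.61 with an estimated correlation). PNO1 and WDR43, both needed to build ribosomes, fell by 0.55 and 0.41. Ribosome biogenesis genes were already lower at 6 h, 7 of 25 and 9 adjusted over the list alone, with a median of -0.18 (camera in limma, Benjamini-Hochberg adjusted p = 2.7e-05, and adjusted p = 0.61 with an estimated correlation). FOSL1 fell by 2.56 and ZEB1 by 0.96. In their list of undifferentiated melanoma 7 of 20 members fell and PDGFRB rose, against 8 and 1 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.00085, and adjusted p = 0.61 with an estimated correlation). ULK1, which starts autophagy, rose by 0.51. Of 28 lysosome and autophagy genes 4 rose, also adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.048, and adjusted p = 0.69 with an estimated correlation). TXNIP and CCNG2, both linked to arrest of growth, rose by 2.0 and 1.62, and the Krüppel-like factor KLF2 fell by 1.66. In their list of cell cycle inhibitors 5 of 16 members rose and 2 fell, against 7 and 4 adjusted over the list alone, with no shift (camera in limma, Benjamini-Hochberg adjusted p = 0.62).

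In all, 2182 of 13506 genes changed at 6 h, 991 higher and 1191 lower (additive limma model of line and treatment, Benjamini-Hochberg threshold 0.05). Of these, 62 rose and 172 fell by at least 2-fold in each line. The error of this test is the disagreement between the 2 lines, so it finds what the lines share. The count was 1398 without the filter on dim genes and 227 when a change beyond 0.5 log2 units was required.

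At 18 h the changes were wider. CEMIP, a hyaluronan-binding protein, fell by 5.52 and COL13A1, a membrane collagen, by 5.36, and DUSP6 (-5.31), ESM1 (-4.84), IL24 (-4.54), SPRY2 (-4.44), ANKRD1 (-4.10), ETV5 (-4.04), CXCL8 (-3.90), MAFF (-3.89), CXCL1 (-3.85) and ETV4 (-3.82) were lowered too. The ERK output list again had 24 of 25 members lower, 24 adjusted over the list alone, with a median of -2.47 (camera in limma, Benjamini-Hochberg adjusted p = 1.2e-14, and adjusted p = 0.61 with an estimated correlation). FOXD3 rose by 4.97, STON1 by 4.61, CD24 by 4.25, GASK1B by 4.19, COL21A1 by 4.10 and SOX2 by 4.05. SP8 (3.83), EDIL3 (3.77), PGM5 (3.76), the melanocortin receptor MC4R (3.70), PRUNE2 (3.56) and ST8SIA4 (3.56) completed the 12 largest increases.

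The cell division and growth programmes were lower at 18 h. All 27 tested genes of G1/S and DNA replication fell, also when adjusted over the list alone, with a median of -0.96 and CDC25A (-2.08), CCNE2 (-2.05), MCM10 (-1.96) and CLSPN (-1.62) in front (camera in limma, Benjamini-Hochberg adjusted p = 1.5e-12, and adjusted p = 0.50 with an estimated correlation). Genes of G2/M and mitosis moved less: 9 of 24 fell, CCNA2 by 0.83 and AURKB by 0.59 among them, and 2 rose, against 7 and 2 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.048, and adjusted p = 0.76 with an estimated correlation). Ribosome biogenesis factors fell in 24 of 25 cases, 24 adjusted over the list alone, with a median of -0.73; LYAR changed by -1.62, MRTO4 by -1.35 and PNO1 by -1.26 (camera in limma, Benjamini-Hochberg adjusted p = 3.4e-10, and adjusted p = 0.61 with an estimated correlation). The ribosomal protein list, which also holds elongation factors such as EEF2, did not follow. Of 47 tested, 4 rose, RPL3 the most at 0.36, none fell and none passed when adjusted over the list alone. The list median was 0.06 with 44 of 47 members above 0, a small rise that the list test did not call (camera in limma, Benjamini-Hochberg adjusted p = 0.093). Among translation initiation factors 13 of 33 fell, such as EIF3B (-0.71) and EIF4A3 (-0.68), and 5 rose, against 15 and 5 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.088). Cell cycle inhibitors and quiescence genes rose in 11 of 16 cases, TXNIP by 2.60 and CCNG2 by 2.0, while KLF2 (-1.85), KLF4 (-1.84) and KLF6 fell, the same counts being found adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.039, and adjusted p = 0.66 with an estimated correlation).

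Stress, interferon and lysosome genes were higher at 18 h. NUPR1 rose by 2.60, the mitochondrial enzyme PCK2 by 2.11 and asparagine synthetase ASNS by 2.07. In the ATF4 list 18 of 33 members rose and PPP1R15A fell, against 19 and 1 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.011, and adjusted p = 0.75 with an estimated correlation). ER chaperone genes moved the other way, 7 of 19 lower with SDF2L1 at -1.05 and MANF at -0.83 and 1 higher, the same counts being found adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.034, and adjusted p = 0.61 with an estimated correlation). IRF9, part of the interferon-activated transcription complex, rose by 1.89, IFIT1 by 1.78, IFIT2 by 1.58 and ISG15 by 1.23. Interferon response genes rose in 11 of 16 cases and fell in 2, also when adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.0060, and adjusted p = 0.61 with an estimated correlation). Lysosome and autophagy genes rose in 17 of 28 cases and fell in 4, against 18 and 4 adjusted over the list alone, with MITF at 1.63, NEU1 at 0.88, HEXA at 0.80 and CTSA at 0.80 (camera in limma, Benjamini-Hochberg adjusted p = 0.0039, and adjusted p = 0.61 with an estimated correlation). TP53INP1 rose by 2.83 and TP53I3 by 1.25, whereas AEN (-1.53) and PLK3 (-1.30) fell. Genes activated by p53 rose in 10 of 16 cases and fell in 3, also when adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.027, and adjusted p = 0.61 with an estimated correlation).

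Melanoma state and receptor genes split at 18 h. In the list of undifferentiated and invasive melanoma 10 of 20 members fell, among them FOSL1 (-3.43), NT5E (-3.24) and the YAP target CCN1 (-1.70), and 5 rose, also when adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.0098, and adjusted p = 0.61 with an estimated correlation). Receptor tyrosine kinases went both ways, 4 of 16 up and 5 down, with the same counts adjusted over the list alone and no shift (camera in limma, Benjamini-Hochberg adjusted p = 0.64): FGFR2 rose by 2.06, ERBB3 by 1.32, PDGFRB by 1.17 and ERBB2 by 1.08, and MET fell. Of 13 pigment cell genes 4 rose, ST6GALNAC2 by 1.04 and GPNMB by 0.89 besides MITF, and 3 fell, MLPH by 0.60, with the same counts adjusted over the list alone and no shift (camera in limma, Benjamini-Hochberg adjusted p = 1.0). In the NF-kB list 7 of 11 members fell, MMP1 by 2.86, and NFKBIA rose, the same counts being found adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.0081, and adjusted p = 0.61 with an estimated correlation). In the BCL2 family BMF, which promotes apoptosis, rose by 1.29, and PMAIP1 (-1.27), MCL1 (-1.23) and BCL2 (-0.75) fell, 3 of 13 being higher and 7 lower, also adjusted over the list alone, with no shift (camera in limma, Benjamini-Hochberg adjusted p = 0.25).

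Metabolic lists did not shift as a whole at 18 h, though members changed. For glycolysis and hypoxia genes 13 of 22 fell, SLC2A3 by 2.22 and ADM by 1.29, and 5 rose, the same counts being found adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.075). For oxidative phosphorylation 10 of 26 rose, NDUFB5 by 0.55, and 5 fell, the coactivator PPARGC1B the most at -1.77, against 12 and 5 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.076). For cholesterol synthesis 6 of 18 fell, HMGCS1 by 0.87 and SQLE by 0.41, and 2 rose, also adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.27). Markers of other cell types were included as a check. The fibroblast markers LUM, DCN and ACTA2 rose by 2.49, 1.78 and 1.72, 3 of 5 tested, also adjusted over the list alone, while the collagen COL1A1 differed by 0.02 (camera in limma, Benjamini-Hochberg adjusted p = 0.048, and adjusted p = 0.61 with an estimated correlation). Of 6 epithelial markers 3 rose, KRT14 by 1.45, and KRT18 fell by 0.78, and of 5 blood cell markers LYZ alone fell, by 0.86, with the same counts adjusted over the list alone and no shift of either list (camera in limma, Benjamini-Hochberg adjusted p-values of 0.58 and 0.66).

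**Figure D2:**
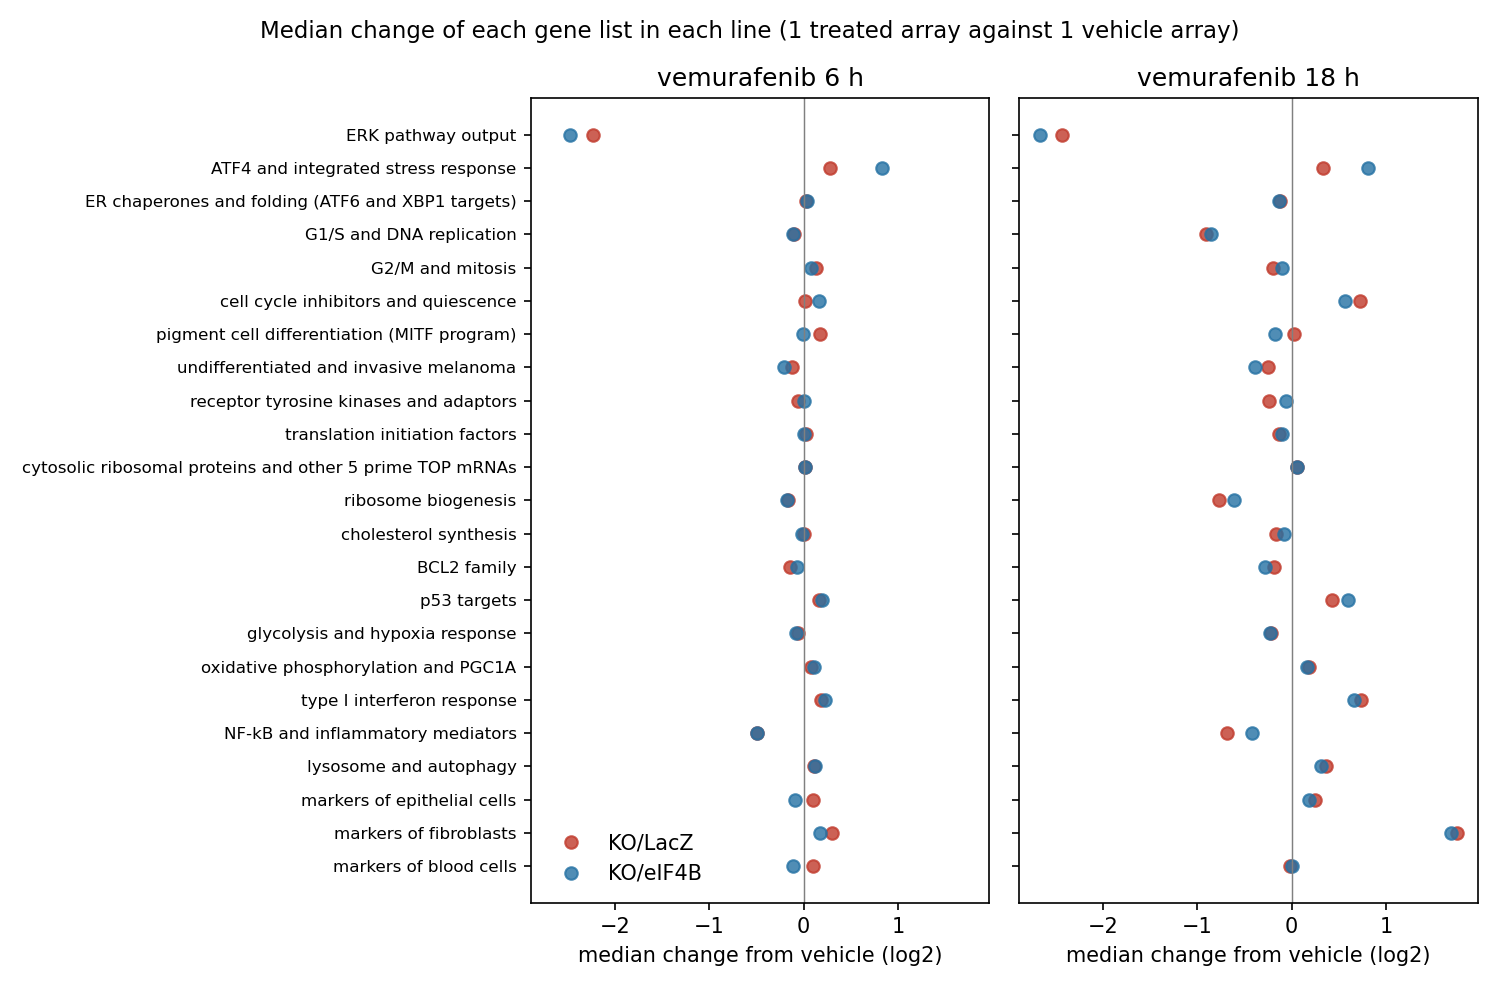
Median log2 change from vehicle (x axis) of each fixed gene list (y axis) after 6 h and 18 h of vemurafenib, knockout line in red and rescued line in blue, each from 1 treated and 1 vehicle array. The ATF4 list lies at 0.28 in the knockout line and 0.83 in the rescued line at 6 h, and at 0.33 and 0.81 at 18 h.

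At 18 h, 6947 of 13506 genes changed, 3797 higher and 3150 lower (additive limma model, Benjamini-Hochberg threshold 0.05), and 495 rose and 355 fell by at least 2-fold in each line. Requiring a change beyond 0.5 log2 units left 1558 genes.

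Changes that grew or faded between the times were tested by setting 18 h against 6 h, with no vehicle array in the comparison. COL21A1 (3.58), PRUNE2 (2.96), EDIL3 (2.84), MGP, an inhibitor of calcification (2.66), PCDH7 (2.63) and IGFBP5 (2.52) were higher at 18 h, and COL13A1 (-3.44), NTM (-3.04), ETV4 (-2.76), NT5E (-2.73), CEMIP (-2.72) and CYB5R2 (-2.72) were lower. Replication genes were lower at 18 h than at 6 h, 26 of 27 of them and 26 adjusted over the list alone, with a median of -0.88 (camera in limma, Benjamini-Hochberg adjusted p = 1.6e-15, and adjusted p = 0.50 with an estimated correlation). Ribosome biogenesis genes were lower in 24 of 25 cases, 25 adjusted over the list alone, with a median of -0.53 (camera in limma, Benjamini-Hochberg adjusted p = 1.5e-11, and adjusted p = 0.61 with an estimated correlation). Interferon genes were higher at 18 h than at 6 h in 11 of 16 cases, also adjusted over the list alone, IRF9 by 1.63 (camera in limma, Benjamini-Hochberg adjusted p = 0.0016, and adjusted p = 0.61 with an estimated correlation). ACTA2 was higher by 1.54, LUM by 1.44 and DCN by 1.39. They were 3 of 5 fibroblast markers, also adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.039, and adjusted p = 0.61 with an estimated correlation). Genes of p53 were higher in 8 of 16 cases and lower in 1, against 10 and 1 adjusted over the list alone, TP53INP1 by 1.58 (camera in limma, Benjamini-Hochberg adjusted p = 0.0060, and adjusted p = 0.61 with an estimated correlation). Lysosome genes were higher in 11 of 28 cases and lower in 2, against 13 and 2 adjusted over the list alone, NEU1 by 0.78 (camera in limma, Benjamini-Hochberg adjusted p = 0.0069, and adjusted p = 0.61 with an estimated correlation). Cell cycle inhibitors were higher in 8 of 16 cases and lower in 1, against 11 and 1 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.0098, and adjusted p = 0.61 with an estimated correlation). Of 24 G2/M genes 10 were lower and 12 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 2.7e-05, and adjusted p = 0.61 with an estimated correlation). Of 19 ER chaperone genes 6 were lower and 1 higher, against 8 and 1 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.013, and adjusted p = 0.61 with an estimated correlation). Of the translation initiation factors 12 of 33 were lower and 4 higher, against 14 and 5 adjusted over the list alone, EIF4A3 at -0.49 (camera in limma, Benjamini-Hochberg adjusted p = 0.027, and adjusted p = 0.61 with an estimated correlation). In the undifferentiated melanoma list 9 of 20 were lower and 4 higher, against 9 and 5 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.050, and adjusted p = 0.61 with an estimated correlation). This was just past the threshold. The ATF4 list did not shift between the times (camera in limma, Benjamini-Hochberg adjusted p = 0.45), though CHAC1 came down by 1.06 (log2 change -1.06) and NUPR1 rose by 1.71. Of its 33 members 4 were higher and 3 lower, against 0 and 1 adjusted over the list alone. Of 13506 genes 4587 differed, 2568 higher and 2019 lower at 18 h, and 240 when a change beyond 0.5 log2 units was required (additive limma model, Benjamini-Hochberg threshold 0.05).

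The next comparison asks how the knockout line differed from the rescued line whatever the treatment, from 3 pairs of arrays. Higher in the knockout line were PGM5 (1.66, SE 0.16), the matrix protein fibronectin FN1 (1.52, SE 0.12), the phosphatase PTPRR (1.44), the potassium channel KCNK1 (1.32), PLAAT1 (1.28), TENM2 (1.18), the neuropeptide ADCYAP1 (1.12), FBXL16 (1.07), GFOD3P (1.01), the growth factor MDK (0.98), the elongation factor EEF1A2 (0.96) and STMN3 (0.95). Lower, besides EIF4B itself, were MAGEB2 (-1.68, SE 0.25), the interferon-induced GTPase GBP1 (-1.30), NAP1L2 (-1.26), CHAC1 (-1.25), the small heat shock protein HSPB8 (-1.22), MAP1B (-1.14), SERPINA3 (-1.11), CD163L1 (-1.09), TM4SF18 (-1.03), SCRG1 (-0.97) and MMP8 (-0.97). All these had the same sign in all 3 pairs.

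Among the fixed lists the ATF4 list stood lowest in the knockout line. Its median difference was -0.29 (camera in limma, Benjamini-Hochberg adjusted p = 2.5e-09, and adjusted p = 0.61 with an estimated correlation). Of its 33 members 2, CHAC1 and DDIT3, were lower over all genes tested, and 14 adjusted over the list alone. The difference was not even across treatments: the median was -0.02 under vehicle, -0.45 at 6 h and -0.52 at 18 h, with 22, 33 and 32 of 33 members lower in the knockout line. Among 10000 expression-matched random lists these medians lay at percentiles 8.0, 0.0 and 0.0. Smaller shifts were seen for G2/M genes, with a median of -0.12 and 0 of 24 called by either adjustment (camera in limma, Benjamini-Hochberg adjusted p = 2.7e-05, and adjusted p = 0.61 with an estimated correlation), and for interferon genes, with MX1 (-0.67), IFI44 (-0.57) and IRF7 (-0.44) lower of 16 and 1 higher and 3 lower adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.025, and adjusted p = 0.61 with an estimated correlation). In the ERK output list CCND1 (-0.47) and FOSL1 were lower, with 4 lower and 1 higher adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.0098, and adjusted p = 0.61 with an estimated correlation). Markers of other cell types also shifted between the lines. Of 5 fibroblast markers 0 passed over all genes and 3 were lower adjusted over the list alone, with a median of -0.25 (camera in limma, Benjamini-Hochberg adjusted p = 0.0069, and adjusted p = 0.61 with an estimated correlation). Of 6 epithelial markers KRT8 was higher by 0.49, and 3 were higher adjusted over the list alone, with a median of 0.27 (camera in limma, Benjamini-Hochberg adjusted p = 0.048, and adjusted p = 0.61 with an estimated correlation). The remaining shifts were small. The G1/S, undifferentiated melanoma, p53, glycolysis and oxidative phosphorylation lists had medians of -0.10, -0.12, -0.06, -0.05 and 0.05. Their members called over all genes were 0, 3, 0, 1 and 0, and adjusted over the list alone 3, 5, 2, 1 and 0 (camera in limma, Benjamini-Hochberg adjusted p-values of 0.016, 0.016, 0.035, 0.026 and 0.038, and each adjusted p = 0.61 with an estimated correlation). The ribosomal protein list had a median difference of 0.02 with 0 of 47 called by either adjustment (camera in limma, Benjamini-Hochberg adjusted p = 0.21). Of the 33 translation initiation factors EIF4B alone was lower, and 2 were lower adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.66).

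In all, 337 of 13506 genes differed between the lines, 194 higher and 143 lower in the knockout line, and 6 were higher and 4 lower by at least 2-fold in every pair (additive limma model, Benjamini-Hochberg threshold 0.05). Without the vehicle, 6 h or 18 h pair the count was 50, 0 and 0. Each of these fits has 1 residual degree of freedom in place of 2, so the drop does not show how much each pair contributed. Without the filter on dim genes the count was 58, and with a filter at 6 log2 units 513. It was 1196 with a trended and robust variance prior. In a test against a minimum difference of 0.5 log2 units EIF4B alone passed. Each line is 1 transduced population, so any other difference between the populations is included.

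The last comparison asks whether the response to vemurafenib differed with eIF4B. Across genes the responses of the 2 lines were alike, with a Pearson r of 0.87 and a Spearman rho of 0.71 at 6 h and 0.94 and 0.89 at 18 h over 13506 genes, which are not independent replicates. The major-axis slope of the knockout line's response on that of the rescued line was 0.99 at 6 h and 1.10 at 18 h. With 1 array per combination a difference in response at a single time has no replicate check and is given as a value only. At 6 h, 20 genes differed in response by at least 1 log2 unit, 1 more positive and 19 more negative in the knockout line. At 18 h there were 57, of which 28 were more positive and 29 more negative.

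The genes named here by the size of the difference have a mean of at least 6 log2 units, apart from EGR1 and VLDLR. Several of the genes with the most negative difference are known ATF4 targets. SLC7A11, the cystine transporter, changed at 6 h by 0.27 in the knockout line and 1.43 in the rescued line, ASNS by 0.84 and 1.91, the mitochondrial folate enzyme ALDH1L2 by 1.20 and 2.47, NUPR1 by 0.31 and 1.46, and VLDLR by 0.92 and 2.65. At 18 h NUPR1 changed by 1.56 and 3.63, ASNS by 1.45 and 2.68, PCK2 by 1.55 and 2.67 and JDP2 by 1.42 and 2.53. The median response of the ATF4 list was 0.28 in the knockout line and 0.83 in the rescued line at 6 h, and 0.33 and 0.81 at 18 h; the median difference in response was -0.41 and -0.50, at percentile 0.0 of random lists both times. The ERK output list responded with medians of -2.24 and -2.48 at 6 h and -2.44 and -2.67 at 18 h. The 2 times share the vehicle arrays, so they are not separate evidence.

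**Figure D3:**
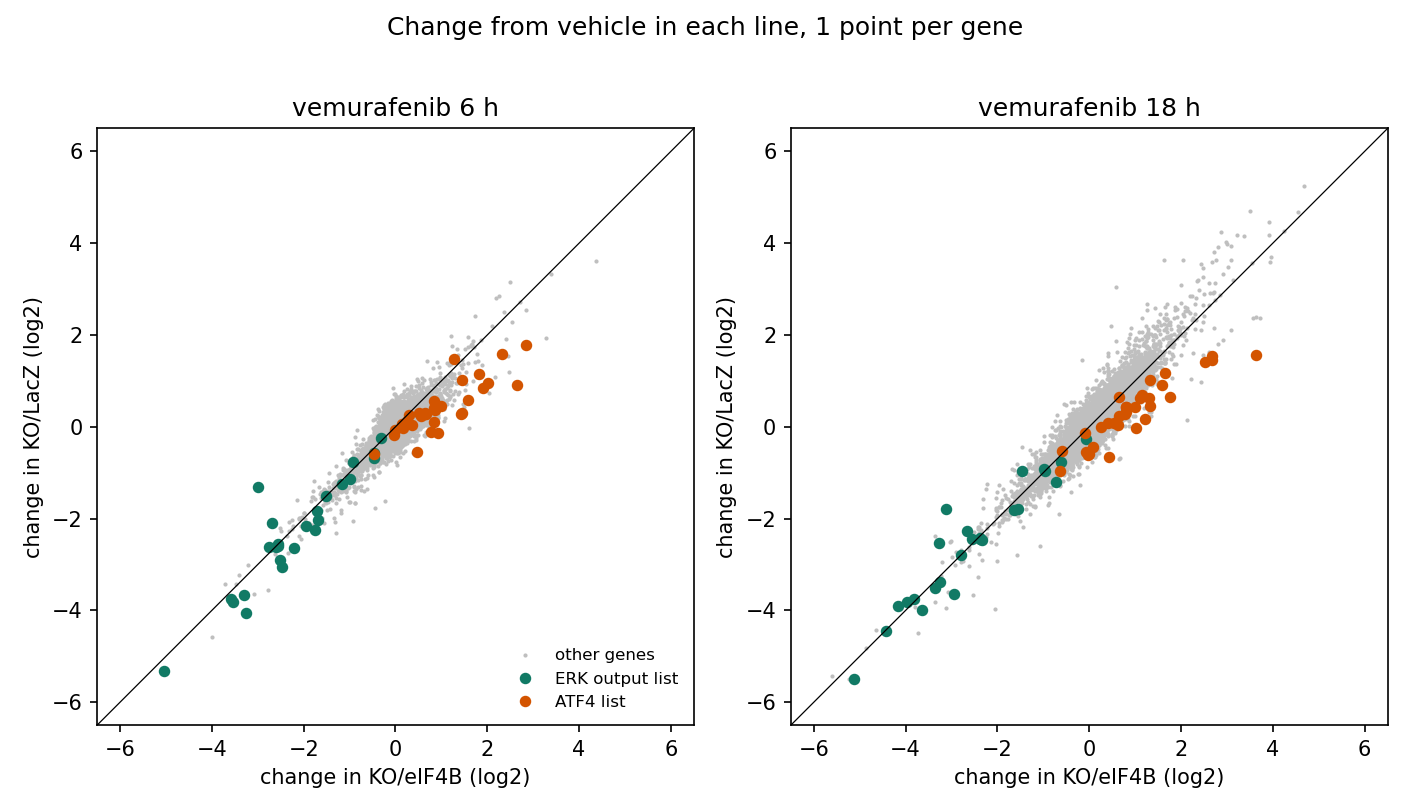
Log2 change from vehicle in the rescued line (x axis) and in the knockout line (y axis) at 6 h and 18 h, 1 point per gene, with the ERK output list in green, the ATF4 list in orange and the line of equal change in black. Most genes lie along that line (r of 0.87 and 0.94), and most ATF4 list members lie below it.

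Other genes also stood out. SLFN5 differed in response at 6 h by -1.63 (-0.03 in the knockout line and 1.60 in the rescued line), ECM2 by -1.36, KLF4, a transcription factor of growth arrest, by -1.31, and the calcium-binding protein S100P by -1.08. EGR1 had the most positive difference at 6 h over all genes tested (1.69). Among genes with a mean of at least 6 log2 units the most positive were MEGF11 (0.66), PCDH10 (0.64), MAP3K5 (0.62), GLDN (0.62), CD5 (0.60), SPRY4 (0.60), MYOZ3 (0.60) and CYP2U1 (0.60). At 18 h, among genes above that mean, the knockout line's response was the more positive for the metalloprotease ADAMTS1 (1.45 against -0.15), PCDH7 (3.63 against 2.05), OGFRL1 (2.68 against 1.26), PRSS33 (2.16 against 0.92), PRRX1 (1.54 against 0.41), SLAIN1 (3.54 against 2.43), ANK3 (3.91 against 2.80) and PCDH18 (3.09 against 1.99). It was the more negative for the secretory granule protein SCG5 (0.15 against 2.13), KLF4 (-2.60 against -1.08), MAGEB2 (-0.71 against 0.66), S100P (2.38 against 3.73), the stress cytokine GDF15 (-0.68 against 0.67), XYLT1 (-1.89 against -0.65) and ECM2 (2.40 against 3.64). Counts of such genes depended on the size asked for and the probe sets used: with a 1.5-fold threshold they were 147 at 6 h (48 more positive and 99 more negative in the knockout line) and 320 at 18 h (205 and 115), and with probe sets averaged per gene 12 and 34.

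A test of the difference in response was possible only by assuming that it was equal at 6 h and 18 h. This leaves 1 residual degree of freedom, and the test was chosen after the data were examined. The 2 vehicle arrays are fitted exactly, so the residual is only the disagreement between the 6 h and 18 h pairs. Its p-values therefore do not measure the spread of the vehicle pair, on which every difference in response rests. By this test 0 of 13506 genes passed (limma, lowest Benjamini-Hochberg adjusted p = 0.81), and 302 had an unadjusted p under 0.05. With limma and Benjamini-Hochberg adjustment 9 passed with a trended and robust variance prior. In simulated data the test recovered 0% of genes that differed by 1 log2 unit and 93.9% of those that differed by 2, and it called 8 unchanged genes. The ATF4 list responded less in the knockout line, with a median of -0.48 (camera in limma, Benjamini-Hochberg adjusted p = 8.1e-36 over 23 lists, and adjusted p = 0.98 with an estimated correlation). Adjusted over the list alone 13 of 33 members had a smaller response in the knockout line and 0 a larger one, PCK2 (-1.09, SE 0.14), JDP2 (-1.08), ASNS (-1.15) and SLC7A11 (-1.10) among them.

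**Figure D4:**
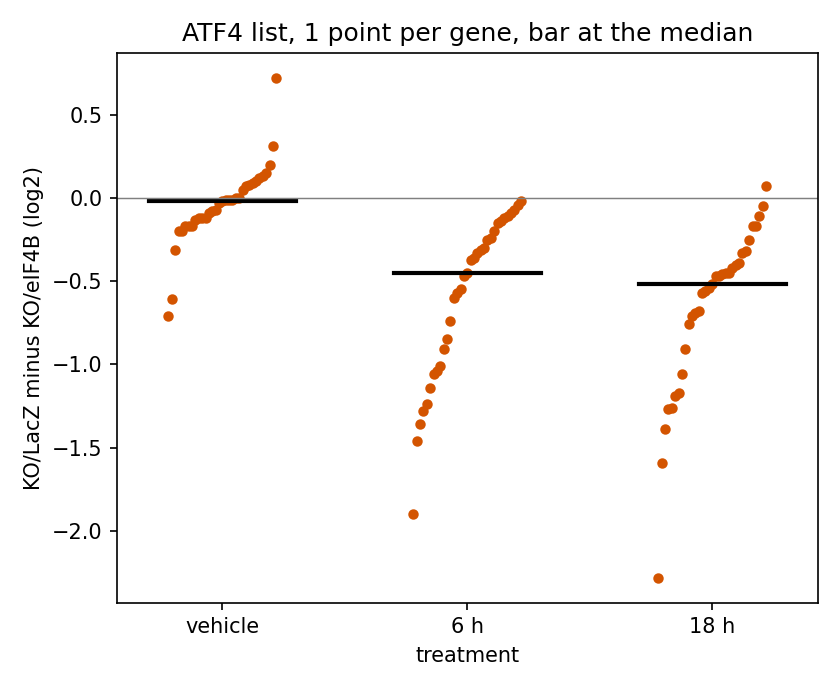
Difference in log2 level between the knockout and the rescued line (y axis, knockout minus rescued) for the 33 tested members of the ATF4 list under each treatment (x axis), 1 point per gene in order of size, with a bar at the median. The medians are -0.02 under vehicle, -0.45 at 6 h and -0.52 at 18 h.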

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

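In this part the tests of the response difference, vehicle arrays, drug action and fibroblast RNA were chosen only after the results were seen. The tests of array scaling, of synthetases and of other splits were set before their own results were seen. Those of scaling and synthetases use the added difference over both times, so they were framed after the data were examined. How far the scalings move genes was computed after the results were seen.

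The ATF4 list drew attention because its response to vemurafenib differed between the lines, with a median difference of -0.48 over both times. The list median, knockout minus rescued, was -0.02 under vehicle (quartiles -0.13 and 0.08) against -0.45 and -0.52 in the treated pairs. With 1 vehicle array per line, a steady difference between the lines plus an odd vehicle array would give the same values. For array scaling, the smaller of the medians after centring and after cyclic loess was -0.46. On values already quantile-normalized these scalings moved 99 of 100 genes by at most 0.02 and could not have removed the difference, so they do not decide. A scaling fault that follows signal level would move expression-matched random lists alike. Their median difference in response was -0.01 at 6 h and at 18 h, against -0.41 and -0.50 for the ATF4 list. These values argue against such a fault as the source. Less drug action in the knockout line stays open too. The ERK output list kept a knockout to rescued ratio of 0.90 at 6 h and 0.91 at 18 h while the ATF4 list had 0.33 and 0.41. Over all genes the slope of the knockout line's response on that of the rescued line was 0.99 at 6 h and 1.10 at 18 h. These slopes argue against a weaker response across genes in the knockout line. With 1 dose ERK output may be blocked fully in both lines, so the values do not decide whether less drug action lies behind the ATF4 difference. An effect of eIF4B on the ATF4 response to the drug also stays open and was not tested. The synthetases induced with ATF4 gave a median of -0.23, but that test asks only how far the difference reaches and not what caused it. Replicate cultures and independent knockout and rescue clones would be needed to test an effect of eIF4B, since each line here is 1 population and each condition 1 array.

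The fibroblast markers LUM, DCN and ACTA2 rose at 18 h in both lines. RNA from fibroblasts would bring collagen mRNAs with it, yet the higher of the lines' median changes of COL1A1, COL1A2 and COL3A1 was 0.03, and COL1A2 and COL3A1 stayed dim with means of 4.72 and 3.41 log2 units. These values argue against fibroblast RNA as the source. A rise of these genes in the melanoma cells is the candidate left, from vemurafenib or from time in culture, which these arrays do not separate.

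For the 337 genes that differed between the lines, the 6 arrays can be parted 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 337 genes and the highest of the other splits 0. Only 4 of the splits, the real one included, part the arrays of every treatment; the other 6 put both arrays of a treatment on one side, so with treatment in the fit they are not comparable.

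The p53 target list also differed in response over both times, by a small median of -0.09 (camera in limma, Benjamini-Hochberg adjusted p = 0.0067, and adjusted p = 0.98 with an estimated correlation). Of its 16 members 0 were called by either adjustment and 2 had an unadjusted limma p under 0.05. Opposite changes at 18 h, not tested, were seen for GDF15 (-0.68 in the knockout line and 0.67 in the rescued line), MAGEB2 (-0.71 and 0.66) and MAP3K5 (0.50 and -0.54).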

How the results depend on the processing

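The test of the response difference over both times was chosen after the data were examined; the other alternatives were set before. With probe sets averaged, other filters or array scalings, the counts at 18 h and for 18 h against 6 h stayed within 1.5 times their values of 6947 and 4587, as did the list calls, at 38 to 46 against 43. With an estimated correlation 0 list calls held; that setting changes both the correlation and the degrees of freedom, and the cause was not tested. At 6 h the 2182 genes became 1398 without a filter. A minimum change of 0.5 log2 units left 227 genes at 6 h, 1558 at 18 h, 240 for 18 h against 6 h and 1 between the lines, by construction a stricter question. The 337 genes between the lines became 58 without a filter, 513 with a filter at 6 and 1196 with a trended and robust prior, and leaving out 1 pair gave 0 to 50, with 1 residual degree of freedom. The cause of the shifts with filter and prior was not tested. Genes past 1 log2 unit in the difference in response went from 20 at 6 h to 12 with probe sets averaged, 11 without ambiguous probe sets and 147 at 1.5-fold, and from 57 at 18 h to 34 with probe sets averaged, 35 with a filter at 6 and 320 at 1.5-fold. The EIF4B difference of -1.68, from the brightest probe set, was -1.67 after centring and -1.69 after cyclic loess. These scalings hardly move quantile-normalized values, so they could not have removed it. The other 2 EIF4B probe sets differed by 0.19 and 0.17, so the difference depends on the probe set used. The ATF4 list's response difference stayed between -0.46 and -0.50 over the alternatives run. Over all genes, the same test called 0 genes in every alternative but the trended and robust prior, with 9. Of the named genes' changes that passed the test, 1 turned its sign under an alternative: IDI1 between 18 h and 6 h, 0.42 from another probe set, and the cause was not tested. Over all alternatives, 4209 values of named genes stayed the same, 142 moved without a test, and 53 lost and 42 gained their call. The counts that stayed and moved include readings of a single line or pair set against the mean, which are no processing alternatives. Of the moved values 57 were such readings of the difference between the lines. Of the list shifts 469 stayed, 62 lost and 21 gained theirs. Signal over background limits which genes can be tested, and 13506 of 19775 passed the filter.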

Other observations

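The synthetase test below was set before its result was seen, and EGR1, TXNIP, CYP1A1, SLC7A11 and TRIB3 were chosen after their values were seen.

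For some genes the lines differed under vehicle and for others under vemurafenib. EGR1, an immediate early gene of ERK signalling, changed at 6 h by -1.31 in the knockout line and -3.0 in the rescued line, but the lines differed under vehicle, by -1.66, and not at 6 h, by 0.03. TXNIP, which restrains glucose uptake, rose by 1.54 and 2.46 at 6 h, with a difference of 1.05 under vehicle and 0.14 at 6 h, and CYP1A1, the aryl hydrocarbon receptor target, changed by -2.32 and -1.30 with a difference of 0.93 under vehicle and -0.09 at 6 h. In the ATF4 list the order was the other way round, with SLC7A11 at -0.13 under vehicle and -1.28 at 6 h and TRIB3 at -0.17 and -1.06. Each of these values comes from 1 array per line.

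If the weaker ATF4 response in the knockout line is general, aminoacyl-tRNA synthetases that are induced with ATF4 but stand outside the fixed list may share it. YARS1, IARS1, LARS1 and TARS1 had a median difference in response over both times of -0.23, and 6 other cytosolic synthetases (FARSA, FARSB, HARS1, KARS1, RARS1 and VARS1) one of -0.07. The direction is that of the hypothesis, but the gap was smaller than the 0.2 log2 units set beforehand, and LARS1 was at -0.03, so the test does not decide.

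Of 7 spike-in control transcripts 3 read higher in the knockout line in every pair. Dap read 8.32, 8.14 and 8.16 log2 units in the knockout line under vehicle, 6 h and 18 h and 7.91, 7.92 and 7.88 in the rescued line, and Phe read 5.96, 5.77 and 5.84 against 5.65, 5.56 and 5.33. Cre read 13.38, 13.35 and 13.36 against 13.33, 13.34 and 13.30. The other 4 did not separate the lines in every pair: Thr read 5.95, 6.40 and 5.64 against 6.12, 6.29 and 5.91, Lys 4.65, 4.5 and 4.66 against 4.56, 4.6 and 4.01, BioB 8.47, 8.28 and 8.33 against 8.26, 8.30 and 8.15, and BioC 9.77, 9.64 and 9.75 against 9.56, 9.64 and 9.58.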
